A study of Oryza sativa with 12 samples.

How the data were processed

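Transcript levels were measured on Affymetrix rice arrays in shoots of hydroponically grown seedlings of 2 rice genotypes, Jijing88 and K83. Seedlings aged 7 days were moved into new medium with or without alkali salts at 50 mM, and shoots were taken 24 h later. Each of the 12 arrays held biotin-labelled total RNA from a pool of 10 shoots. Plants grew in a greenhouse with 16 h of light at 27 °C and 8 h of darkness at 23 °C. The labels' genotype and stress entries put the arrays into 4 groups of 3 biological replicates.

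The deposited values are log2 signals, 1 per probe set and array. The submitters' processing notes name RMA and limma, with no versions or roles. The log base is not stated there and was read from the values, whose range and near-equal quartiles in every array are those of RMA output. No further normalization was applied. The table holds 57381 probe sets, of which 123 control probe sets were left out of the tests, leaving 57258. Arrays give no read depth, and their number, 3 per group, limits the precision.

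Differences were tested per probe set with limma 3.58.1 in R 4.3.3, from a fit of 4 group means with no covariates (8 residual degrees of freedom) and moderated variances. All 12 arrays entered the fit, which gives every contrast a shared estimate of the spread. The 5 contrasts were alkali minus control in Jijing88, alkali minus control in K83, the difference between those effects (K83 minus Jijing88), K83 minus Jijing88 in control, and K83 minus Jijing88 under alkali. P-values were adjusted by the Benjamini-Hochberg method over all probe sets of a contrast, and an adjusted p under 0.05 is called a change. Tests are two-sided. A group mean below the array medians was taken as close to background, and a difference from it as a lower bound. Values per group are means with the standard deviation over 3 arrays.

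Genes were assigned from the array's annotation table and a RefSeq gene table for the Japonica group, with 22436 probe sets assigned to 1 gene, 95 to several and 34727 to none. Of the 17905 genes, 2457 have a name beyond a locus number. A gene was read from its probe set with the highest mean over the 12 arrays. Gene positions are those of the RefSeq table, whose assembly need not be the one behind the array design.

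A set of 30 gene lists was fixed before the data were examined, as were the contrasts, the tests, the rule for named genes and the alternatives, except those said to be added. The background of the list test was set later, before any group was compared. The lists covered abscisic acid (ABA), LEA proteins and dehydrins, osmolyte synthesis, antioxidant enzymes, glutathione S-transferases, photosystems and the Calvin cycle, chlorophyll synthesis, chlorophyll breakdown and senescence, iron uptake and transport, phosphate starvation, sodium, potassium and proton transport, jasmonate, ethylene, auxin response, cytokinin response, NAC, WRKY and AP2/ERF transcription factors, heat shock proteins, nitrogen uptake and assimilation, the cell cycle, cell wall growth, aquaporins, cytosolic ribosomal proteins, pathogenesis-related proteins with diterpenoid phytoalexins, starch and sucrose metabolism, organic acid metabolism, and markers of root, seed and meristem. The annotation carries no gene descriptions, so that members were found by gene names and synonyms, with name patterns written after the annotation was read and before any group was compared. Members without a name in the annotation are therefore missing from the lists. Lists with at least 5 measured genes were tested with limma's camera at its preset inter-gene correlation of 0.01, against the 2457 named genes, with adjustment over the lists of a contrast. Each call is given with its adjusted p under a correlation estimated from the data, and counts of members are given over all probe sets and adjusted over the list alone.

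The named genes are, for each alkali effect, the 8 with the largest rise and the 8 with the largest fall among called genes with a name whose treated arrays all lie on 1 side of the control arrays, with up to 3 called members of each list, or the member with the smallest p where none is called. For the other contrasts they are the 6 largest in each direction, with no rule on overlap for the difference between the effects. At most 2 genes with only a locus number are named per direction. The text names a part of these and gives the rest as counts.

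The pipeline was tested on simulated arrays with the means and residual spreads of the real probe sets. Noise was drawn independently for each probe set, with the same spread in all 4 groups. The simulation thus does not show how the test behaves where spreads differ between groups, as they do for some real genes. With no change simulated it made 0 calls in each contrast. Then 200 probe sets were changed by known sizes, and 4 to 9 unchanged probe sets were called per contrast. Of simulated changes of 1 on the log2 scale it recovered 92.9% in the Jijing88 contrast, 87.1% in the K83 contrast and 69.0% in the difference between them, and of changes of 0.5 it recovered 34.8%, 33.3% and 8.33%. Fewer probe sets were changed than were called in any real contrast. The adjustment depends on that number, so that these rates need not hold for the real contrasts.

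Alternatives covered a replicate block, fits with the groups of 1 contrast, a filter on dim probe sets, quantile normalization and median centring, another variance model, array weights, leaving out probe sets that can match several genes, stricter thresholds, other list tests, and leaving out each array in turn. Those chosen after seeing the data left out both Jijing88 alkali arrays with high ribosomal RNA signal, or set the lists against all genes. The former leaves a single Jijing88 alkali array, so that no conclusion is drawn from its counts for contrasts with that group. Its calls of genes and lists are not given for those contrasts. RNA quality was read from the control probe sets, by the difference of 3' and 5' signals and by the ribosomal RNA signal, with exact permutation tests.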

Results

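Shoot transcripts were measured on 12 Affymetrix rice arrays from the genotypes Jijing88 and K83, each in control medium and after 24 h with alkali salts at 50 mM. There were 3 arrays per group, each labelled a biological replicate and from a pool of 10 shoots, and their number limits the precision. The labels do not say what arrays of the same replicate number share across groups. Of 18 such pairs, 7 had deviations from their group means with a correlation above 0.1 across probe sets. Array medians lay between 5.12 and 5.18 on the log2 scale. The correlation between arrays of a group, taken across probe sets, which are not independent replicates, was 0.993 to 0.997. The first principal component held 48.97% of the variance and placed Jijing88 arrays at -63.4 to -19.4 and K83 arrays at 31.7 to 59.3. The second held 19.59% and placed control arrays at -45.0 to -6.53 and alkali arrays at 15.1 to 40.1. The 25S ribosomal RNA control signal was 9.68, 7.87 and 9.44 in Jijing88 alkali replicates 1, 2 and 3, beside 8.05 ± 0.19 (SD, n = 3) in Jijing88 control arrays, a difference that did not pass (two-sided exact permutation test, p = 0.3, smallest possible 0.1). Jijing88 control replicate 3 stood apart in iron genes, with a NAS1 signal of 13.42 beside 11.43 and 9.96 in replicates 1 and 2.

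The first comparison asked how shoots of Jijing88 respond to the alkali salts. The labels give neither the composition of the salts nor the pH, and no group had a neutral salt. Here and below, effects of alkalinity, of salt and of osmotic stress therefore cannot be told apart. Genes of the glyoxylate cycle had the largest rises among named genes over all 12 arrays. ICL (LOC4343441, chromosome 7, 20918662 to 20921302), isocitrate lyase, rose 12.5-fold from 3.99 ± 0.11 to 7.64 ± 1.71 (SD, n = 3; adjusted p = 0.00129). MS (LOC9268154, chromosome 4, 24822494 to 24824975), malate synthase, rose 10.5-fold from 6.81 ± 0.39 to 10.20 ± 1.56 (SD, n = 3; adjusted p = 0.00137). In K83 control and alkali arrays the SD was 0.10 and 0.09 for ICL and 0.03 and 0.15 for MS (n = 3). The fit shares a spread over the 4 groups, so that both adjusted p take too small a spread for Jijing88 alkali. Without Jijing88 alkali replicate 1 the log2 rise was 2.83 for ICL and 2.71 for MS, and without replicate 2 it was 4.54 and 4.24, a range that overlaps that of GLT2 (2.56 to 3.49) when each array was left out. In replicates 1, 2 and 3 the rise was 5.25, 1.85 and 3.82 for ICL and 4.75, 1.69 and 3.72 for MS, in the order of their 25S ribosomal RNA signal. In K83, where that signal was 8.27 ± 0.23 in alkali and 8.32 ± 0.24 in control arrays (SD, n = 3), the rise was 3.79 to 3.98 for ICL and 1.78 to 2.08 for MS. GLT2, a glutamate synthase of nitrogen assimilation, rose 7.74-fold (adjusted p = 0.000123), ASMT1, an N-acetylserotonin methyltransferase of melatonin synthesis, 6.39-fold (adjusted p = 3.28e-06), and the protein kinase gene CIPK14 5.67-fold (adjusted p = 0.000108). The control signals of ICL (3.99) and ASMT1 (3.81) lay near the 25th percentile of the arrays (3.95 to 3.997), close to background, so that their folds are to be read as lower bounds. Among falling genes were VIT1.2, a vacuolar iron transporter (-2.13, adjusted p = 0.00198), RR1, a type A response regulator of cytokinin signalling (-1.99, adjusted p = 8e-05), and GluTR, glutamyl-tRNA reductase of chlorophyll synthesis (-1.59, adjusted p = 0.000366). Of genes with only a locus number, LOC4324218 rose by 4.55 from a control signal of 5.06, below the array medians, and LOC4350534 fell by 3.62. In all, 4789 of 57258 probe sets were called, 2456 higher and 2333 lower. At least 2-fold, 802 changed, 613 higher and 189 lower.

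The cell cycle list was the called list in Jijing88. Of its 43 genes 1 rose and 8 fell, or 1 and 21 adjusted over the list alone, with a mean of -0.24 (adjusted p = 0.000485; adjusted p = 0.78 with an estimated correlation). CYCD5-1, a D-type cyclin, was the member that rose, by 0.92. The other 27 tested lists did not pass, with adjusted p from 0.17 to 0.999, and in 10 of them the mean, median and test differed in sign. By fry, which tests against no change, some of them passed. Higher were the osmolyte list (adjusted p = 0.0117) and the LEA, iron and ethylene lists (adjusted p = 0.0234 each). Lower were the heat shock (adjusted p = 0.037) and cell wall growth (adjusted p = 0.0383) lists. Without Jijing88 control replicate 3 the jasmonate list (mean 0.55, adjusted p = 0.0212), the ribosomal protein list (mean -0.12, adjusted p = 0.00511) and the iron list passed.

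Of 24 abscisic acid (ABA) genes 4 rose and 1 fell (5 and 2 adjusted over the list alone), among them OsABA1 of ABA synthesis (1.15) and the receptor gene PYL11 (0.51). Of 8 LEA genes 2 rose, EM (2.01) and RAB21 (1.14), and 2 did so adjusted over the list alone. Of 13 osmolyte genes 2 rose (3 adjusted over the list alone), among them P5CS2 of proline synthesis (1.29), for which 2 of 3 further probe sets had the opposite sign. Of 22 antioxidant genes 1 rose and 2 fell, with the same counts adjusted over the list alone, among them the catalase gene CAT-A (0.44) and the ascorbate peroxidase gene APX1 (-0.94). Of 6 glutathione S-transferase genes 1 rose and 1 fell (2 and 2 adjusted over the list alone), with GSTZ5 at 0.61. Of 35 jasmonate genes 6 rose and 1 fell (8 and 1 adjusted over the list alone), with the repressor genes JAZ9 (2.12) and JAZ5 (1.72). Of 11 ethylene genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), with ACO1 of ethylene synthesis at 0.75. Of 28 genes for pathogenesis-related proteins and phytoalexins 3 rose, and 3 adjusted over the list alone, with the chitinase genes Cht6 (1.53) and CH16 (1.45).

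Of 58 auxin response genes 3 rose and 6 fell (4 and 7 adjusted over the list alone), among them IAA2 (1.07) and ARF24 (-0.83). Of 31 cytokinin response genes 4 rose and 5 fell (5 and 5 adjusted over the list alone), RR1, RR9 (-1.69) and RR6 (-1.35) among them. Of 8 NAC genes 2 rose (3 adjusted over the list alone), with NAC45 at 1.38. Of 6 WRKY genes none was called by limma over all probe sets and 2 rose adjusted over the list alone, with WRKY71 at 1.36 (adjusted p = 0.0824). Of 10 AP2/ERF genes 1 rose, as it did adjusted over the list alone. Of 25 heat shock genes 3 fell (6 adjusted over the list alone), with HSP24.1 at -1.27 and HSP17.4 at -1.09.

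Among transport and metabolism lists, 8 of 26 iron genes rose and 1 fell (11 and 1 adjusted over the list alone), with the iron transporter gene IRT1 at 1.77 (adjusted p = 0.00921), and the list did not pass (mean 0.42, adjusted p = 0.17). Without Jijing88 control replicate 3, the array with high iron genes, it passed (mean 0.59, adjusted p = 0.0212). Of 22 phosphate genes 5 rose and 2 fell (8 and 5 adjusted over the list alone), with SPX1 at 0.72. Of 32 sodium, potassium and proton transport genes 3 rose and 3 fell, as they did adjusted over the list alone, with the potassium transporter gene HAK10 at 0.87. Of 17 nitrogen genes 3 rose and 3 fell (4 and 3 adjusted over the list alone), with the ammonium transporter gene AMT2-1 at 1.42. Of 25 aquaporin genes 4 rose and 2 fell, as they did adjusted over the list alone, with OsPIP1;3 at 1.11 and the silicon channel gene Lsi6 at -1.13. Of 29 starch and sucrose genes 4 rose and 3 fell (6 and 5 adjusted over the list alone), with the sucrose synthase gene SUS4 at 1.04. Of 4 organic acid genes 2 rose and 1 fell (2 and 2 adjusted over the list alone), ICL and the malic enzyme gene ME6 (-0.60) among them, too few for a list test.

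In the chloroplast lists, 2 of 15 photosystem and Calvin cycle genes rose and 1 fell, also adjusted over the list alone, with the light-harvesting genes CAB2R (0.49) and LHCP (0.48). Of 15 chlorophyll synthesis genes 1 rose and 1 fell (2 and 1 adjusted over the list alone), namely PORA (1.12), a protochlorophyllide reductase gene, and GluTR. Of 5 genes of chlorophyll breakdown 1 rose and 1 fell, also adjusted over the list alone, with NYC1, a chlorophyll b reductase gene, at -0.97. Of 59 cell wall growth genes 1 rose and 9 fell (2 and 11 adjusted over the list alone), with CSLE1 at 1.71. Of 23 ribosomal protein genes none was called by limma, over all probe sets or adjusted over the list alone. Among markers of other tissues, 0 of 3 root, 1 of 10 seed and 0 of 16 meristem genes were called, with the same counts adjusted over the list alone. Without Jijing88 control replicate 2 the count of called probe sets was 2666.

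The next comparison asked how K83 shoots respond. Among genes with a name, the iron uptake gene Nramp1 had the largest rise. Nramp1 (LOC4342862, chromosome 7, 9047200 to 9052036), a metal transporter gene, rose 29.4-fold from 7.15 ± 0.02 to 12.03 ± 0.13 (SD, n = 3; adjusted p = 2e-06). IRT2 (LOC4333667, chromosome 3, 27143873 to 27145246), an iron transporter gene, rose by 3.95 from 4.15 ± 0.29 to 8.10 ± 0.30 (SD, n = 3; adjusted p = 9.17e-06). The nicotianamine synthase genes NAS1 (LOC4332608) and NAS2 (LOC4332607), neighbours on chromosome 3, rose by 3.42 (adjusted p = 0.00462) and 3.14 (adjusted p = 0.00326), and the transcription factor gene BHLH063 rose 7.63-fold (adjusted p = 0.000452). ICL rose 14.9-fold (adjusted p = 0.0012), with a log2 range of 3.84 to 3.95 when each array was left out that overlaps that of IRT2 (3.84 to 4.12), and EM, a LEA protein gene, 9.69-fold (adjusted p = 0.000251). The K83 control signals of IRT2 (4.15), ICL (4.05), EM (4.06) and NAS1 (4.67) lay below the array medians and close to background, so that these rises are to be read as lower bounds. Of genes with only a locus number, LOC4351985 rose by 6.51 and LOC4333962 by 5.595, also from control signals of 4.29 and 4.65 below the array medians, and LOC4350534 fell by 3.91. NIA1, nitrate reductase, fell by 1.92 (adjusted p = 6.06e-06), with -0.01 at a further probe set, and the auxin transporter gene PIN5A fell by 1.75 (adjusted p = 4.8e-07). Of 57258 probe sets 3700 were called, 1493 higher and 2207 lower, or 1281 and 2842 under median centring. At least 2-fold, 498 changed, 346 higher and 152 lower. The difference of 3' and 5' actin signals, a sign of RNA quality, was 2.18 ± 0.08 in K83 alkali arrays and 1.98 ± 0.15 in K83 control arrays (SD, n = 3; two-sided exact permutation test, p = 0.1, the smallest possible).

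**Figure D1:**
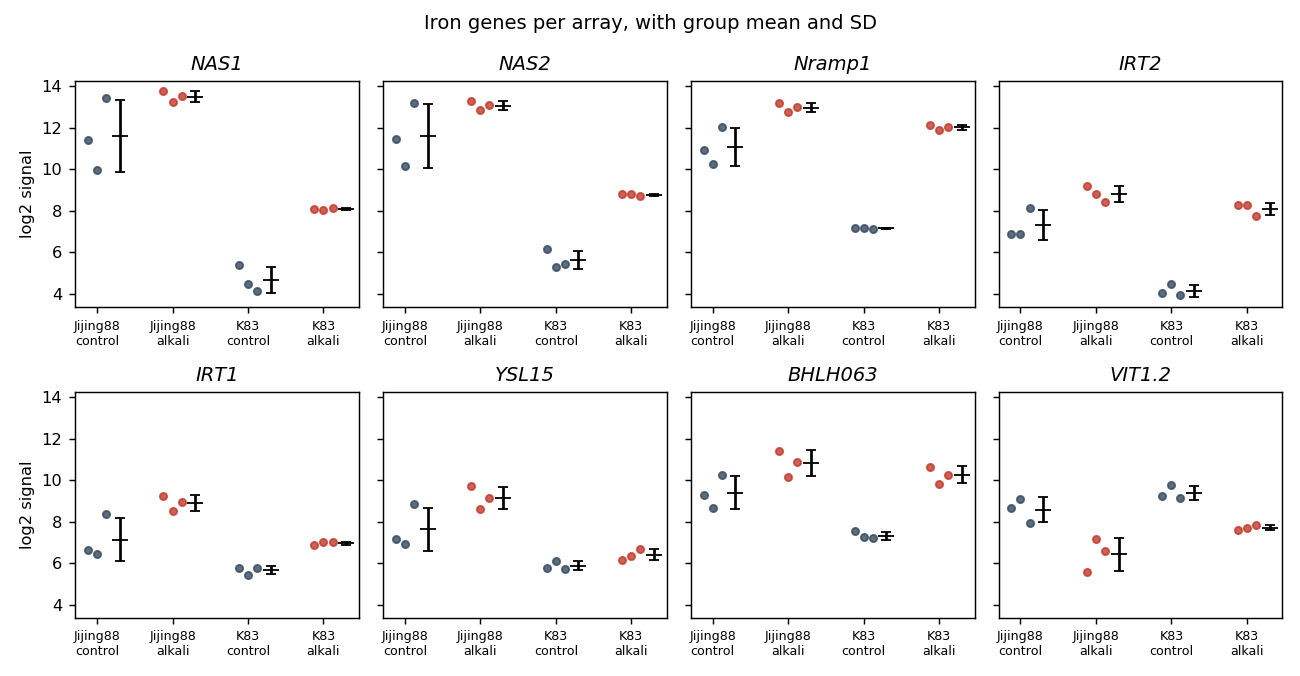
Log2 signal of 8 iron genes by group, with a point for each array and bars for the group mean and SD (n = 3). Nramp1 was at 7.15 in K83 control and 12.03 in K83 alkali, and at 11.08 and 12.98 in Jijing88.

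The iron list rose in K83. Of its 26 genes 5 rose and 4 fell (9 and 4 adjusted over the list alone), with a mean of 0.57 (adjusted p = 0.014; adjusted p = 0.361 with an estimated correlation). Nramp1 and BHLH063 are not members. The cell cycle list fell, with 1 of 43 genes rising and 23 falling (1 and 29 adjusted over the list alone) and a mean of -0.41 (adjusted p = 1.17e-06; adjusted p = 0.361 with an estimated correlation). Its replication genes ORC3 (-0.96), RPA70B (-0.92) and ORC1 (-0.90) fell. The LEA list rose, with 5 of 8 genes rising and 1 falling (6 and 1 adjusted over the list alone), a mean of 1.10 (adjusted p = 0.0019; adjusted p = 0.118 with an estimated correlation), LEA19 at 2.73, a lower bound from a control signal of 3.90 close to background, and RAB21 at 1.80.

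In the list of pathogenesis-related proteins and phytoalexins 4 of 28 genes rose (5 adjusted over the list alone), with a mean of 0.27 (adjusted p = 0.00461; adjusted p = 0.548 with an estimated correlation) and the chitinase gene Cht10 at 0.63. In the jasmonate list 6 of 35 rose (7 adjusted over the list alone), with a mean of 0.41 (adjusted p = 0.00598; adjusted p = 0.548 with an estimated correlation) and JAZ5 at 1.34. By fry, which tests against no change, neither of these lists passed (adjusted p = 0.165 and 0.158). In the ethylene list 3 of 11 rose (4 adjusted over the list alone), with a mean of 0.35 (adjusted p = 0.0094; adjusted p = 0.361 with an estimated correlation), ACS2 at 1.28 and ACO1 at 0.85. In the aquaporin list 6 of 25 rose (6 rose and 1 fell adjusted over the list alone), with a mean of 0.21 (adjusted p = 0.0228; adjusted p = 0.229 with an estimated correlation; 0.101 with dim genes left out), OsPIP2;7 at 0.86, and TIP3 at 1.35, a lower bound from a control signal of 4.49 below the array medians. The ribosomal protein list fell, with 1 of 23 genes called, also adjusted over the list alone, and a mean of -0.17 (adjusted p = 0.00461; adjusted p = 0.642 with an estimated correlation). The other 20 tested lists did not pass, with adjusted p from 0.0679 to 0.986, and in 3 of them the mean, median and test differed in sign. Called members of those lists included the kinase gene SAPK9 (0.97), the phosphate regulator gene PHR3 (1.42), the potassium channel gene AKT1 (0.78), AMT3-2 (1.77), GH3-8 of auxin conjugation (1.40) and RR5 (-0.95).

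Without K83 control replicate 3 and without K83 alkali replicate 1 the heat shock list passed in K83 (adjusted p = 0.0239 and 0.0215), as did the phosphate list without K83 alkali replicate 2 (adjusted p = 0.0209). The heat shock list was also lower by fry with all arrays (adjusted p = 0.00419). The count in K83 was 2457 without K83 control replicate 1, 1721 without K83 control replicate 2, and 2210, 1887 and 1831 without K83 alkali replicates 1, 2 and 3.

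The third comparison asked whether the genotypes differ in their response. Nramp1 rose more in K83, by a difference of 2.98 (adjusted p = 0.0122), having been at 11.08 ± 0.92 (SD, n = 3) in Jijing88 control. NAS1 and NAS2 had changes of 1.90 (adjusted p = 0.076) and 1.46 (adjusted p = 0.118) in Jijing88. Their responses did not differ past the threshold in limma (adjusted p = 0.458 and 0.333), nor did that of BHLH063 (adjusted p = 0.204). In Jijing88 NAS1 was at 11.43, 9.96 and 13.42 in control replicates 1, 2 and 3, and at 13.23 to 13.76 under alkali. NAS2 was at 11.47, 10.15 and 13.22 in those control arrays, and at 12.87 to 13.28 under alkali. With control replicate 3 at the alkali level, the missed calls do not show that NAS1 and NAS2 failed to respond or responded alike. ELA3 (LOC4341858) differed by 2.88 (adjusted p = 0.00767) and ILL8 (LOC4342839), an auxin conjugate hydrolase gene, by 1.45 (adjusted p = 0.00244). In the other direction, ASMT1 (LOC4346795, chromosome 9, 15078949 to 15080612) rose in Jijing88 by 2.67 and differed by -2.19 (adjusted p = 0.00168). PORA (LOC4337415, chromosome 4, 35182937 to 35184574) moved from 8.96 ± 0.20 to 10.08 ± 0.12 in Jijing88 and from 10.10 ± 0.21 to 9.53 ± 0.10 in K83 (SD, n = 3), a difference of -1.69 (adjusted p = 0.0014). OsABA1 differed by -1.47 (adjusted p = 0.00406). The clock genes PRR95 and CCA1 differed by -1.66 (adjusted p = 0.00579) and -1.77 (adjusted p = 0.0142), with 0.18 at a further probe set of CCA1.

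Called changes overlapped between the genotypes. Of the probe sets called higher, 824 were shared where independence gives 64.0, and of those called lower 699 where it gives 89.9, while 37 were called in opposite directions. Independence was taken over all 57258 probe sets, dim ones included. Both contrasts also share a spread per probe set, so that part of the excess can arise without a shared response. The changes had r = 0.53 across all probe sets and 0.70 across those called in either, which were selected for their changes, and probe sets are not independent replicates. The test of the difference called 360 probe sets, 153 with a higher and 207 with a lower value in K83 (110 and 304 under median centring; 343 and 303 without Jijing88 control replicate 3), and 8023 had an unadjusted p under 0.05. Of the 360, 162 were called in Jijing88 alone, 120 in K83 alone, 40 in both with the same sign and 37 in both with opposite signs.

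**Figure D2:**
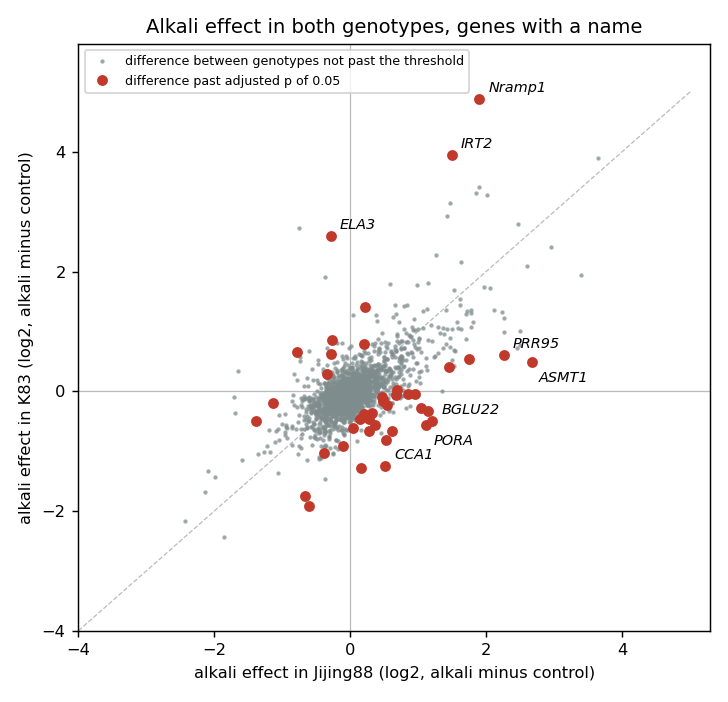
Alkali effect in K83 against that in Jijing88, both as log2 change, with a point for each of 2457 named genes and the 42 past the threshold for the difference in red. Nramp1 lies at 4.88 in K83 and 1.90 in Jijing88, and ASMT1 at 0.49 and 2.67.

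The lists called were LEA proteins, with 0 of 8 genes called by limma over all probe sets and 5 adjusted over the list alone (4 higher, 1 lower) and a mean of 0.75 (adjusted p = 0.0442; adjusted p = 0.395 with an estimated correlation), and cell wall growth, with 0 of 59 called, also adjusted over the list alone, and a mean of 0.07 (adjusted p = 0.0442; adjusted p = 0.725 with an estimated correlation). With a replicate block their adjusted p was 0.107 and 0.0601, with the mean of all probe sets of a gene 0.137 and 0.0504, and, as an alternative chosen after seeing the data, 0.0614 for both against all genes. By fry the cell wall growth list had 0.553 and the LEA list 0.0251. The osmolyte list, not called by camera, was lower by fry (mean -0.28, adjusted p = 0.0193). The LEA list had 0.0677 without Jijing88 control replicate 3, 0.078 and 0.0674 without Jijing88 alkali replicates 1 and 3, 0.0771 and 0.0749 without K83 control replicates 1 and 3, and 0.0634 without K83 alkali replicate 1. The cell wall growth list had 0.14 without Jijing88 control replicate 3, 0.078, 0.061 and 0.0602 without Jijing88 alkali replicates 1, 2 and 3, 0.0767 and 0.0749 without K83 control replicates 1 and 3, and 0.0593 without K83 alkali replicate 1. The cell cycle list, which fell in each genotype, did not differ past the threshold (mean -0.16, adjusted p = 0.22), except without Jijing88 control replicate 2 (adjusted p = 0.0349). In that fit the ribosomal protein (0.0349), auxin response (0.0373) and aquaporin (0.0497) lists passed too, and auxin response did without Jijing88 alkali replicate 2 (0.0466). With all 12 arrays the lists called in K83 and not in Jijing88, other than LEA proteins, did not differ past the threshold by camera. Their adjusted p was 0.671 for iron, 0.527 for jasmonate, 0.572 for ethylene, 0.266 for pathogenesis-related proteins, 0.127 for aquaporins and 0.22 for ribosomal proteins. In 9 of the lists not called the mean, median and test differed in sign. The count of 360 was 186 and 646 without Jijing88 control replicates 1 and 3, 197 and 189 without Jijing88 alkali replicates 1 and 3, 124 and 130 without K83 control replicates 2 and 3, and 143, 136 and 107 without K83 alkali replicates 1, 2 and 3.

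The genotypes were then compared in control medium, to give the baseline. Several iron genes were lower in K83. NAS1 was at 4.67 ± 0.65 in K83 and 11.60 ± 1.74 in Jijing88 (SD, n = 3), a difference of -6.94 (adjusted p = 5.93e-06), and NAS2 differed by -5.98 (adjusted p = 6.32e-06), Nramp1 by -3.93 (adjusted p = 2.5e-06) and IRT2 by -3.16 (adjusted p = 1.44e-05). NAS1 and IRT2 (4.15) in K83 control lay below the array medians and close to background, so that the size of their differences is to be read as a lower bound. BURP16 (LOC4348595) was lower by -4.33 (adjusted p = 1.23e-08). The zinc transporter genes ZIP3 (LOC4338051) and ZIP4 were higher in K83, by 2.47 (adjusted p = 2.19e-08) and 2.37 (adjusted p = 9.51e-07), as was ORC1 (LOC4340349, chromosome 6, 4557620 to 4565403), a subunit gene of the replication origin complex, by 2.13 (adjusted p = 5.74e-07). The annotation gives the name ZIP3 to several genes, and the one read here lies on chromosome 5. Of 57258 probe sets 6658 were called, 3541 higher and 3117 lower, or 4276 and 2702 under median centring.

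The cell cycle list was higher in K83, with 22 of 43 genes higher and 0 lower (29 and 1 adjusted over the list alone) and a mean of 0.68 (adjusted p = 1.1e-10; adjusted p = 0.541 with an estimated correlation). The chlorophyll synthesis list was higher, with 5 of 15 genes (8 adjusted over the list alone) and a mean of 0.40 (adjusted p = 0.0103; adjusted p = 0.869 with an estimated correlation). Lower in K83 were the jasmonate list, with 4 of 35 genes lower, also adjusted over the list alone, and a mean of -0.21 (adjusted p = 0.0133; adjusted p = 0.869 with an estimated correlation), and the nitrogen list, with 6 of 17 lower and 1 higher (7 and 1 adjusted over the list alone) and a mean of -0.47 (adjusted p = 0.025; adjusted p = 0.76 with an estimated correlation). The iron list was lower too, with 10 of 26 lower and 2 higher, also adjusted over the list alone, and a mean of -0.86 (adjusted p = 0.0298; adjusted p = 0.76 with an estimated correlation). In 6 of the lists not called the mean, median and test differed in sign. Without Jijing88 control replicate 3 the chlorophyll synthesis and jasmonate lists both had an adjusted p of 0.118, and the iron list had 0.0625 without K83 control replicate 1 and 0.0613 without both high ribosomal RNA arrays, chosen after seeing the data. By fry the jasmonate list had 0.145. Lists not called by camera that were higher by fry were osmolytes (adjusted p = 0.0104), chlorophyll breakdown (0.0189) and cytokinin response (0.0262). The sodium, potassium and proton transport list was lower by fry (adjusted p = 0.0189).

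The last comparison gave the genotype difference under alkali. NAS1 remained lower in K83, by -5.42 (adjusted p = 5.01e-05), NAS2 by -4.31 (adjusted p = 0.000104) and BURP16 by -5.05 (adjusted p = 2.38e-09), as was YSL15, a transporter gene of iron chelates, by -2.75 (adjusted p = 0.000398). Nramp1 differed by -0.95 and did not pass (adjusted p = 0.0613). CPS2 and DTS2 of diterpenoid synthesis were higher in K83, by 3.31 (adjusted p = 0.00441) and 2.26 (adjusted p = 0.00971), as were LEA19 by 2.55 (adjusted p = 0.00725) and ELA3 by 2.25 (adjusted p = 0.000128). CPS2 (4.06) and LEA19 (4.08) were close to background in Jijing88 alkali, so that their differences are to be read as lower bounds. The cell cycle list was the called list, with 24 of 43 genes higher and 1 lower (27 and 3 adjusted over the list alone) and a mean of 0.51 (adjusted p = 1.57e-07; adjusted p = 0.832 with an estimated correlation). In 8 of the lists not called the mean, median and test differed in sign. By fry the LEA (adjusted p = 0.00124) and aquaporin (0.021) lists were higher and the iron list lower (0.00473). Of 57258 probe sets 8188 were called, 4035 higher and 4153 lower in K83.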

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

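The tests of meristem markers and of genes with no further probe set above the median, the held-out form of the ribosomal RNA test, and the splits on residuals were chosen only after the results were seen.

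The test of the difference of the alkali effect between the genotypes called 360 probe sets. Of 100 splits that exchange genotype labels within a condition 4 gave at least as many, the real one included. The others had 1072, 949 and 373 calls, each with all alkali labels and 1 control array per genotype exchanged. The genotype difference thus enters their contrast itself. In the 88 splits that mix both conditions it enters the spread, and 73 of them gave 0 calls in limma. These splits therefore decide nothing about chance. With the additive genotype and alkali effects taken out first 1 of the same 100 splits, the real one, gave as many (highest other 291, with 0 calls in 72 of the 88). That form does not exclude chance, since the other splits keep as little as 0.5556 of their contrast's variance, the real one all of it. With all 4 group means taken out 1 of 89, the real one, gave as many (highest other 0). For independent noise the other splits then keep at least 0.8889 of the variance of their contrast and at most 0.7778 of the residual variance. Under independent noise, lost contrast variance thus does not account for their lack of calls. The real split was read on the values and the others on residuals, so that this form does not exclude chance either. A shift common to the arrays of a group goes out with its mean and stays open. High ribosomal RNA signal in Jijing88 alkali replicates 1 and 3 could bring the difference, and the median ratio of the difference with replicate 2 as the lone treated Jijing88 array to the full one, 0.955, decides nothing, since the probe sets were called with that array. Over probe sets called without replicate 2 the ratio was 0.752 (spread 0.0155), at the bound of 0.75 and not beyond its spread, beside 0.946 and 0.947 for the other arrays, with the same sign in 97.96%, so that a part brought by those arrays and a response of the genotype cannot be told apart. A different response of the genotypes stays open as the biological explanation.

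Genes named for that difference had values of 2.98 for Nramp1, 2.88 for ELA3, 2.45 for IRT2, 1.45 for ILL8, 1.18 for GH3-8, 1.14 for OsPIP2;7, -2.19 for ASMT1, -1.77 for CCA1, -1.71 for BGLU22, -1.69 for PORA, -1.66 for PRR95 and -1.47 for OsABA1, each from a tested difference between the genotypes. IRT2 in K83 control (4.15) and ASMT1 in both control groups (3.81 and 3.75) lay close to background, so that the exact size of their values is uncertain. When each of the 12 arrays was left out in turn, IRT2 lost its call in 5 cases (highest adjusted p = 0.0696), GH3-8 in 11 (0.0999), OsPIP2;7 in 10 (0.103) and BGLU22 in 10 (0.106). The LEA list had a mean difference of 0.75 and the cell wall growth list of 0.0666.

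Genotype differences in control at 2-fold or more could come from sequence differences under single probe sets. In the 64 genes with a further probe set above the median, 93.7% of 79 further probe sets went the same way (95% exact interval 85.8 to 97.9), beside 93.2% for the alkali effect in Jijing88, which argues against this for those genes. The interval counts probe sets of the same gene as independent, so that it may be too narrow. For the 608 genes with no further probe set above the median the explanations cannot be told apart, since 569 have no further probe set and those of the other 39 were too dim to be read. A genotype difference in transcript level stays open as the biological explanation.

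The cell cycle list was higher in K83 than in Jijing88 in control, which might come from a larger share of meristem tissue in the K83 shoots. The meristem markers above the array median had a median difference of -0.0769, where the cell cycle list had 0.59. They are 2 genes, after 4 broadly expressed class II KNOX genes were left out, so that tissue share and expression per cell cannot be told apart.

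For the other comparisons there are 10 splits of 6 arrays, too few for a share under 0.05, and in each 1 split, the real one, gave as many calls. The real value and the highest other were 4789 and 1 for alkali in Jijing88, 3700 and 0 for alkali in K83, 6658 and 25 for the genotypes in control, and 8188 and 23 under alkali.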

How the results depend on the processing

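The fit without both Jijing88 alkali arrays of high ribosomal RNA signal, and the lists against all genes, were chosen only after the results were seen; for the counts that moved, the cause was not tested except where fewer arrays or a stricter threshold show it. With a replicate block the counts were 5075 and 3872 for alkali in Jijing88 and K83, 322 for the difference, 6873 and 8337 for the genotypes in control and under alkali, and 15 lists beside 17. A fit of the groups of the contrast alone gave 2768 in Jijing88. At 2-fold the counts were 802 (613 higher, 189 lower), 498 (346 higher, 152 lower), 143, 1269 and 1391, in the same order, and at an adjusted p under 0.01 they were 2257, 1392, 56, 3644 and 4692. The difference had 626 calls with dim probe sets left out, 656 with trend and robust variances, and 658 with array weights. Under median centring it had 110 higher and 304 lower, beside 153 and 207. Leaving out both high ribosomal RNA arrays leaves a single Jijing88 alkali array, with no spread of its own. Lower counts in that fit therefore decide nothing about what those arrays bring. Without both high ribosomal RNA arrays the counts were 1857 in Jijing88, 43 for the difference and 3465 for the genotypes under alkali. With an estimated correlation camera called 0 lists, and fry, which does not compare a list with other genes, called 29 and lost 4 of the 17: jasmonate (0.158) and pathogenesis-related proteins (0.165) in K83, cell wall growth for the difference (0.553) and jasmonate in control (0.145). The aquaporin list in K83 had an adjusted p of 0.101 with dim genes left out. Against all genes 16 lists were called. The cytokinin list in K83, with a mean of -0.0801 in both tests, was down relative to no change in fry (adjusted p = 0.0258). In camera its direction was up at an adjusted p of 0.976, which shows no shift relative to other genes. The list mean lay below and the list median (-0.0338) above the median of all named genes (-0.0476). Leaving out each array in turn gave 2666 to 5463 in Jijing88, 1721 to 4693 in K83, 107 to 646 for the difference, 4551 to 6764 and 5879 to 9105 for the genotypes in control and under alkali, and 14 to 21 lists. Of named genes called, 61 of 83 in Jijing88, 54 of 78 in K83, 8 of 12 for the difference and 12 of 12 for each genotype difference were called in every such fit. A pseudocount on the log scale was not run, since the values are log2 already. Signal near the background limits small changes in dim probe sets.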

Other observations

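The clock topic was chosen only after the results were seen, while its test was written before the 5 values were read.

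Core clock genes other than CCA1 and PRR95 responded to alkali in part. PRR1, the rice relative of the evening gene TOC1, rose in both genotypes, by 0.59 in Jijing88 (adjusted p = 0.000465) and by 0.37 in K83 (adjusted p = 0.0127). PRR73 rose by 0.39 in Jijing88 (adjusted p = 0.0132), with 0.18 in K83 (adjusted p = 0.263). GI and PCL1 rose in K83, by 0.36 (adjusted p = 0.044) and 0.43 (adjusted p = 0.0149), with 0.18 (adjusted p = 0.333) and 0.22 (adjusted p = 0.186) in Jijing88. PRR37 had changes of 0.27 (adjusted p = 0.143) and 0.14 (adjusted p = 0.525). In control shoots all 5 were lower in K83 than in Jijing88, by -0.31 for PRR1 (adjusted p = 0.0197) to -0.52 for PRR73 (adjusted p = 0.00144). None of the 5 was called for the difference of the alkali effect between the genotypes, with adjusted p from 0.408 to 0.731 in limma and 0 of 5 at an unadjusted p under 0.05.

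The difference of the alkali effect in CCA1 and PRR95 could come from another clock phase at harvest in some of the groups, from the hour of harvest or otherwise. The median absolute difference of the 5 other clock genes was 0.206, above that of 83.5% of 10000 random sets of 5 named genes of like signal and below their 95th percentile of 0.266. The bound of 0.3 set beforehand lies above that percentile, so that most random sets would meet it and the test decides nothing. A phase shift and a response of these genes themselves cannot be told apart with 5 genes at a single hour.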
